A study of Arabidopsis thaliana with 28 samples.

How the data were processed

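Whole 7-day-old Arabidopsis thaliana seedlings of the wild type Col-0 and of a pif7 mutant were profiled by RNA sequencing under long days (16 h light, 8 h dark). Seedlings grew either at a constant 17 °C or under a daily cycle that held 27 °C from ZT4 to ZT12 and 17 °C for the rest of the day, where ZT is the number of hours after lights on. Libraries were collected at ZT0, ZT4, ZT5, ZT8, ZT12, ZT16 and ZT20, with 1 library for each combination of genotype, regime and time, 28 in all. The labels give 27 °C for every library of the oscillating regime, also at times outside the warm part of the day, and the libraries were placed in that regime from the growth protocol. The allele of pif7 is not named.

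Per the submitters' processing notes, reads were aligned with HISAT2 to TAIR10 and quantified with StringTie, with no versions, strand setting or options stated. The deposited tables of gene abundance give, per the file headers, a coverage (a depth of signal per base), an FPKM value and a TPM value for each gene. The authors deposited FPKM beside TPM, and the coverage and FPKM columns were used only to derive the sequencing depth. The deposited TPM column is treated as another unit than standard TPM, since assembled loci sum to 1000000 in each library and the 33602 reference genes, listed again, sum to between 1010427 and 1034801. Only the reference gene rows were tested. The depth derived from coverage and FPKM ran from 1.32 gigabases (Col-0, oscillating, ZT0) to 2.82 gigabases (pif7, oscillating, ZT5), with a median of 1.85 in the 14 Col-0 libraries and 2.08 in the 14 pif7 libraries. Read counts were not used here, so no counting interval is given. Gene symbols were taken from the RefSeq annotation, which matched 32835 of the 33602 genes.

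TPM values were rescaled by median-ratio factors, a pseudocount of 1 was added, and log2 values were fitted with limma 3.58.1 in R 4.3.3 with a variance trend. Genes with a TPM of at least 1 in at least 2 libraries were tested, which left 21031. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. Regime differences were fitted with a term for each genotype and time, averaged over the warm window (ZT5, ZT8 and ZT12) or over the times outside it (ZT0, ZT4, ZT16 and ZT20), in each genotype, in both together, and as the difference between genotypes. Each time was also fitted alone over both genotypes, genotype differences were fitted with a term for each regime and time, and time of day was tested in the 14 constant libraries with a term for genotype. With 1 library per condition the residual spread comes from differences between times and between genotypes, so p measures how constant a difference was across them and not the spread between pools of seedlings. Errors are standard errors from the fit.

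For 19 gene lists fixed before the data were examined, limma's camera was run with a preset correlation of 0.01 and again with an estimated correlation, and members were also counted with p adjusted over the list alone. Genes were named by a rule fixed at the same time. PIF7 came first. Each comparison then named up to 10 genes with the highest and 10 with the lowest log2 difference among those past the threshold, with a mean TPM of at least 5 and the same sign in every pair. Up to 4 members per list with the largest absolute difference followed, with every member of the PIF and phytochrome list, and YUC8, IAA19, IAA29, ATHB2, HSP70-4 and HSFA2. If fewer than 5 genes passed, the 5 with the smallest p were also taken. For time of day the rule took the clock list and the 3 genes of largest amplitude per peak time. Not every gene named by the rule is described below. The levels of JAZ10 and AOC1 in single libraries were chosen after their values were seen.

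The fits were tested on simulated data. There 66% of genes with a genotype-by-regime difference of 1 log2 unit were recovered, and 95% of those with 2. The simulated difference was equal at every window time, and the noise had the spread of the pif7 minus Col-0 differences. Regime effects that vary between times, which widen the errors in the data, were not simulated. Recovery in the data can be lower, so a lack of calls does not show a lack of differences. Delays in time of day were estimated by shifting each gene's constant-regime course, in steps of 0.5 h up to 6 h, to the best correlation with its oscillating course, and a simulated delay of 1.5 h was recovered as 1.5 h. Alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter, a mean TPM of at least 5, unscaled TPM, quantile normalization, no variance trend, leaving out each time, and fitting only the pairs of a comparison. Omission of the Col-0 ZT5 pair, restriction to nuclear genes, removal of a gene length trend and left-out times for gene lists were added after seeing the data. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.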

Results

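Gene expression was measured in whole seedlings of Col-0 and pif7 at 7 times of day under constant 17 °C and under a regime that was warmed to 27 °C between ZT4 and ZT12. Each of the 28 conditions has 1 library and there are no replicates. The depth was 1.32 to 2.82 gigabases per library. The comparisons ask how seedlings respond to a warm daytime, and which part of that response depends on PIF7, a basic helix-loop-helix transcription factor of shade and warmth signalling.

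PIF7 (AT5G61270, TAIR10 chromosome 5, 24638773 to 24640600, minus strand) was lower in pif7 than in Col-0 in all 14 pairs, by a log2 difference of -1.54 ± 0.10 (SE, adjusted p = 2.26e-08). It stayed detectable, at 1.91 to 13.1 TPM in pif7 against 8.42 to 38.6 TPM in Col-0. The level in pif7 was 31.8% of that in Col-0 at the median over the 14 pairs and 49.4% at most. PIF7 itself did not pass the test between regimes in the warm window (log2 difference 0.06 ± 0.22, adjusted p = 0.885).

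Time of day shaped a large part of the transcriptome at constant temperature. LHY and CCA1, the morning MYB factors of the clock, peaked at ZT0 with amplitudes of 8.24 and 7.41 log2 units, and PRR7 and FKF1 peaked at ZT8 with 6.63 and 6.25. COL2, a relative of the flowering regulator CONSTANS, peaked at ZT0 with 6.94, and RVE2, a MYB factor related to CCA1, at ZT20 with 5.41. Of the 26 clock genes tested, 24 varied with time, also when adjusted over the list alone, and RVE6 and ZTL did not pass. All 19 light-harvesting antenna genes, 20 of 21 flavonoid genes and 15 of 18 cold response genes varied with time, with 19, 21 and 15 adjusted over the list alone. Over all genes, 6429 of 21031 (30.6%) passed in limma, and 3887 of these (60.5%) peaked at the same sampled time in both genotypes.

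In the warm window, chaperone genes rose together in both genotypes. HSP70-4, a cytosolic heat shock protein, was 15.4-fold higher (log2 difference 3.95 ± 0.72 SE, adjusted p = 0.0025, higher in 6 of 6 pairs), and HSP90.1, HSP23.5 and HSP17.4 had log2 differences of 3.93, 3.76 and 3.67. MBF1C, a heat-responsive coactivator, and HOP3, a co-chaperone, rose by 3.41 and 3.44. Without ZT5 HSP70-4, HSP90.1, HSP23.5, HSP17.4, MBF1C and HOP3 had log2 differences of 2.22, 2.24, 2.18, 2.38, 2.36 and 2.33, and without ZT12 HSP70-4 had 4.89. PDF2.1, a defensin, fell to 0.117 of its level in the constant regime. LTI30, a cold-induced dehydrin, fell by 2.35 on the log2 scale, and RD29A, a dehydration and cold gene, fell by 2.06. RD29A did not pass without ZT8 (-1.35, adjusted p = 0.194), and had -2.68 without ZT12. Across both genotypes 2149 genes rose and 1935 fell. This total of 4084 was 1256 without ZT8, 2021 without ZT12, and 2323 when only the pairs of the comparison were fitted.

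Of the 36 heat shock genes tested, 23 rose in the warm window over both genotypes (30 adjusted over the list alone), with a median log2 difference of 1.41. The list's adjusted p was 4.45e-13, and adjusted p = 0.272 with an estimated correlation. Of the 18 cold response genes 9 fell (9 adjusted over the list alone), with a median of -0.83 and adjusted p = 0.272 with an estimated correlation. Of 32 auxin genes 17 rose and 1 fell (18 and 2 adjusted over the list alone, adjusted p = 0.204 with an estimated correlation). Of 21 genes associated with PIFs in shade and growth 10 rose (12 adjusted over the list alone, adjusted p = 0.194 with an estimated correlation). Of the 8 PIF and phytochrome genes 4 rose (4 adjusted over the list alone, adjusted p = 0.307 with an estimated correlation). Of 14 cell wall loosening genes 7 rose and 1 fell (8 and 1 adjusted over the list alone, adjusted p = 0.194 with an estimated correlation), and 2 of 4 gibberellin and brassinosteroid synthesis genes rose (2 adjusted over the list alone, adjusted p = 0.194 with an estimated correlation).

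Among the other lists in the same comparison, 8 of 21 flavonoid and anthocyanin genes fell (11 adjusted over the list alone, adjusted p = 0.318 with an estimated correlation). Of 13 salicylic acid and defence genes 4 fell (4 adjusted over the list alone, adjusted p = 0.204 with an estimated correlation). Of 13 jasmonate genes 4 fell and 1 rose (4 and 1 adjusted over the list alone, adjusted p = 0.486 with an estimated correlation). Of 12 abscisic acid and dehydration genes 4 rose and 1 fell (5 and 1 adjusted over the list alone, adjusted p = 0.205 with an estimated correlation). Of 4 genes induced by dark and sugar starvation 2 rose (3 adjusted over the list alone, adjusted p = 0.295 with an estimated correlation). All 3 seed storage markers tested rose (3 adjusted over the list alone, adjusted p = 0.159 with an estimated correlation). The clock list had 7 of 26 genes higher (7 and 1 lower adjusted over the list alone), and the list did not pass (adjusted p = 0.079). The photoperiod and flowering list had 1 gene higher and 4 lower of 12 (3 and 4 adjusted over the list alone, adjusted p = 0.913). The light-harvesting antenna had 0 of 19 past limma's test (0 adjusted over the list alone, adjusted p = 0.758), and light signalling had 1 of 17 lower (0 adjusted over the list alone, adjusted p = 0.683). Root markers had 2 higher and 3 lower of 19 (2 and 4 adjusted over the list alone, adjusted p = 0.318), and stomatal lineage markers 2 lower of 7 (2 adjusted over the list alone, adjusted p = 0.596). Over the left-out times, gibberellin and brassinosteroid synthesis (0.0996) and jasmonate (0.474) did not pass without ZT5, nor the dark and sugar list without ZT12 (0.066). The clock list passed without ZT5 (0.0123) or ZT8 (0.0236), and the antenna list without ZT12 (0.0332).

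**Figure D1:**
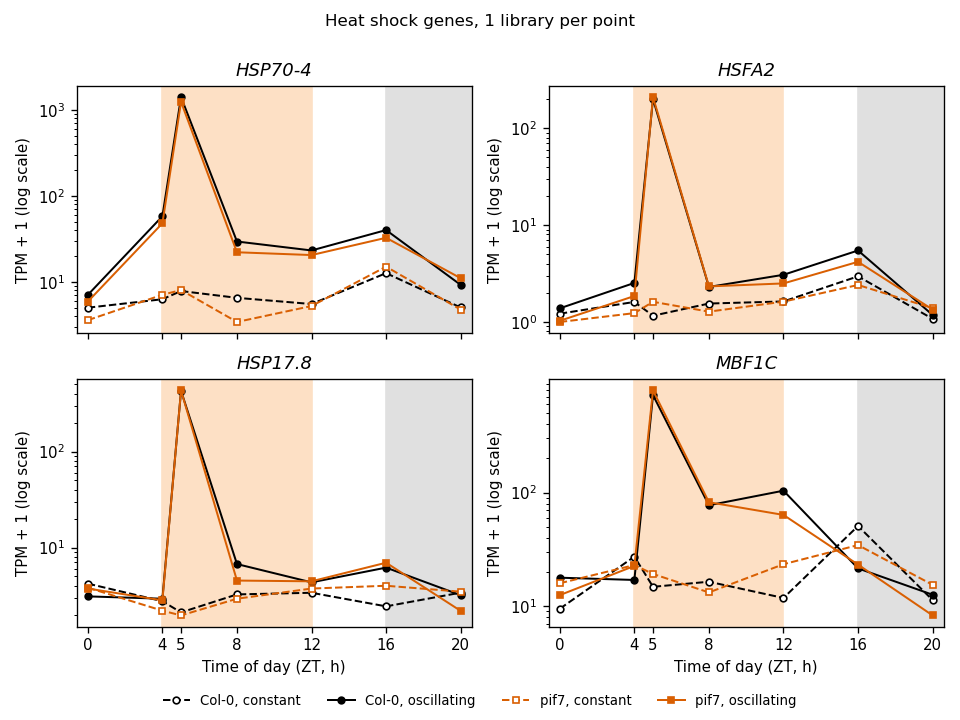
TPM + 1 on a log axis against time of day for 4 heat shock genes, with 1 library per point, Col-0 in black, pif7 in orange, constant regime dashed and oscillating regime solid, the warm window shaded orange and darkness grey. HSP70-4 reached 1410 TPM in Col-0 and 1240 TPM in pif7 at ZT5 of the oscillating regime.

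In Col-0 alone, growth-related auxin genes stood among the highest differences of the warm window. IAA29, an auxin-induced repressor, had a log2 difference of 2.82 ± 0.42 (SE, adjusted p = 0.0041, higher in 3 of 3 pairs), and SAUR22 and SAUR19, small auxin-induced growth genes, 2.81 and 2.59. HFR1, a helix-loop-helix factor of shade responses, rose by 2.53, and YUC8, an auxin synthesis enzyme, by 1.35. Without ZT8 none of the 5 passed, with IAA29, SAUR22, SAUR19 and HFR1 between 2.19 and 2.29 and YUC8 at 0.98 (adjusted p = 0.0762 to 0.145). Without ZT5 IAA29, SAUR22 and HFR1 had 3.66, 3.68 and 3.28. Of the 32 auxin genes 13 rose and 1 fell (21 and 2 adjusted over the list alone, adjusted p = 0.0609 with an estimated correlation). In total 563 genes rose and 364 fell. The total of 927 was 23 without ZT8, 451 without ZT12, 547 without ZT20 and 2 when only the pairs of the comparison were fitted.

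In pif7 the warm window raised the same kind of chaperone genes, with HSP23.5 at 4.14, HSP90.1 at 4.05 and HSP70-4 at 3.96 log2 units. Without ZT5 all 3 passed, with HSP23.5 at 2.49 and HSP90.1 at 2.55. HSP90.1 and HSP70-4 did not pass without any other single time (adjusted p up to 0.128 and 0.15), nor HSP23.5 without ZT8, ZT12 or ZT20 (up to 0.0725). IAA29 and YUC8 did not pass there, with log2 differences of 0.25 ± 0.42 and -0.18 ± 0.24. HFR1 had a ratio of 2.63 (3 of 3 pairs higher), and SAUR19 and SAUR22 log2 differences of 1.49 ± 0.46 and 0.95 ± 0.48, and none of the 3 passed (adjusted p = 0.0516, 0.0882 and 0.283). Without ZT5 HFR1 and SAUR19 passed, with log2 differences of 1.79 and 2.31. Of the 21 PIF-associated genes 1 rose (3 adjusted over the list alone), with 17 above 0 (adjusted p = 0.0132, adjusted p = 0.354 with an estimated correlation), and the list did not pass without ZT12 (0.0775). Of the 32 auxin genes 0 rose and 1 fell (0 and 1 adjusted over the list alone, list adjusted p = 0.0722, but 0.0479 without ZT0 and 0.045 without ZT12). All 3 seed storage markers rose in pif7 (3 adjusted over the list alone, median 1.83), at mean TPM of 0.544 to 3.87. This was the only list to pass there with an estimated correlation (adjusted p = 0.0337). In Col-0 1 rose (2 adjusted over the list alone, adjusted p = 0.159 with an estimated correlation). ATHB2, a homeobox gene of shade responses, rose by 0.79 in pif7 and by 0.88 in Col-0. ATHB2 passed in neither without ZT8 or without ZT12, nor in pif7 without ZT0 or ZT16 (adjusted p = 0.0633 to 0.259). In total 484 genes rose and 311 fell, and the total of 795 was 29 without ZT8, 192 without ZT12, 388 without ZT20 and 0 (4216 at an unadjusted p under 0.05 with all pairs in limma) when only the pairs of the comparison were fitted. Across genes, which are not independent replicates, the effects in the genotypes had r = 0.816. In both genotypes 471 genes passed, all in the same direction, against 18.3 for independent tests. Both tests share the residual variance of each gene, so 18.3 is not their chance level.

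The difference between the genotypes' warm window effects was tested directly. The auxin list rose less in pif7, with a median difference of -0.68 log2 units and 26 of 32 members below 0 (adjusted p = 3.4e-17, adjusted p = 0.0193 with an estimated correlation). By time, auxin medians in Col-0 and pif7 were 0.41 and 0.29 at ZT5, 1.09 and 0.24 at ZT8, and 0.98 and 0.13 at ZT12. Outside the window they were 0.34 and -0.28 at ZT0, in the window's direction, and 0.13 and 0.59 at ZT4, the other way round. Over both genotypes the auxin median was 0.11 at ZT16 and 0.28 at ZT20 (adjusted p = 0.371 and 0.00649). With an estimated correlation these were 0.724 and 0.555. IAA29 and YUC8 had differences of -2.57 ± 0.59 and -1.53 ± 0.33, neither past the test over all genes. The PIF-associated list had a median of -0.36 with 21 of 21 members below 0, cell wall loosening -0.39, and gibberellin and brassinosteroid synthesis -0.31 (adjusted p = 0.0216, 0.0216 and 0.0348 with an estimated correlation). The jasmonate list differed the other way by 0.79, with 13 of 13 members above 0, and the seed storage markers by 0.70 (adjusted p = 0.027 and 0.0148 with an estimated correlation), and the jasmonate median was 0.27 without ZT5. Root markers had a median of -0.21 with 4 of 19 members above 0, and stomatal lineage markers 0.15 with 5 of 7 (adjusted p = 8.64e-05 and 0.0207, adjusted p = 0.193 with an estimated correlation for both). Without ZT12 the root markers turned to the other direction (adjusted p = 0.901), and the stomatal lineage markers did not pass without ZT8 or without ZT12 (0.192 and 0.874). Light signalling had a median of -0.22 with 1 of 17 above 0, and cold response 0.19 with 13 of 18 (adjusted p = 0.00727 and 0.0209, adjusted p = 0.285 and 0.608 with an estimated correlation). Cold response turned to the other direction without ZT5 (0.864) and did not pass without ZT8 (0.246). Light signalling did not pass without ZT5 or ZT12 (0.34 and 0.232), nor gibberellin and brassinosteroid synthesis without ZT12 (0.134). The heat shock list did not pass (median 0.02, adjusted p = 0.825), nor did the clock list (median 0.04, adjusted p = 0.60). No list but auxin (2 genes) and seed storage (2 genes) had a member past the test adjusted over the list alone. By limma 0 of 21031 single genes passed, with 278 at an unadjusted p under 0.05, and 4 passed without ZT12. The 5 genes with the smallest p included AT5G05250 (1.61 ± 0.31) and AT5G44440 (-3.02 ± 0.64), which did not pass.

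**Figure D2:**
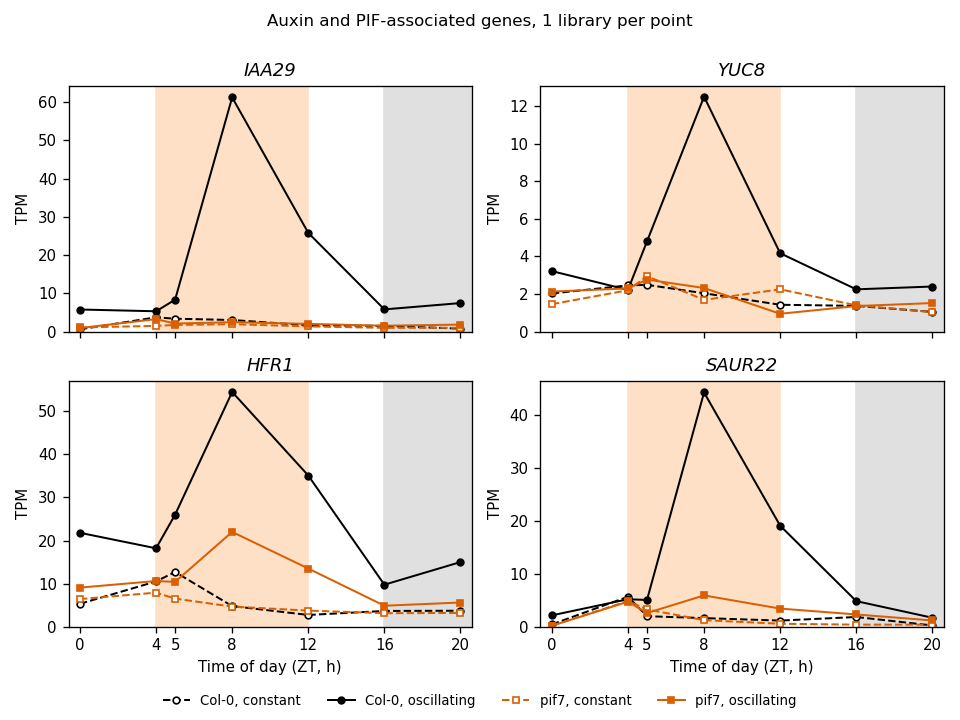
TPM against time of day for IAA29, YUC8, HFR1 and SAUR22, with 1 library per point, Col-0 in black, pif7 in orange, constant regime dashed and oscillating regime solid, the warm window shaded orange and darkness grey. At ZT8 of the oscillating regime IAA29 stood at 61.2 TPM in Col-0 and 2.47 TPM in pif7.

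The response moved through the day. At ZT5, 1 h after the step to 27 °C, heat shock genes were among those with the highest differences, and HSP17.8, HSP70-4, HSP90.1 and HSFA2, a heat shock transcription factor, had log2 differences of 7.76, 7.41, 7.31 and 7.26. Of the 36 heat shock genes 35 rose (36 adjusted over the list alone, adjusted p = 6.34e-06 with an estimated correlation). At ZT8 the median of the list was 0.54, with 16 higher and 1 lower (19 and 3 adjusted over the list alone, adjusted p = 0.00916 with an estimated correlation). At ZT8 SAUR22, SAUR19 and HFR1 had risen by 2.83, 2.63 and 2.58, and FKF1, a blue light receptor of the clock, had fallen by 3.85. The cold genes COR15B and RD29A fell by 4.32 and 3.48 at ZT8, when 15 of 18 cold response genes were lower (16 adjusted over the list alone, adjusted p = 0.136 with an estimated correlation). Over the whole warm window FKF1 and COR15B did not pass in limma (-1.39 and -1.67, adjusted p = 0.0848 and 0.104), with 2 of 6 pairs higher for each. For genes that vary with time of day, a difference at a single time cannot tell a change of level from a delay.

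At ZT12 PIF4, a close relative of PIF7, rose by 3.16 ± 0.19 (SE, adjusted p = 4.86e-06), from 10.7 to 79.7 TPM in Col-0, and the kinase gene CIPK20 was 19.7-fold higher. Of the 26 clock genes 14 were higher and 1 lower at ZT12 (15 and 1 adjusted over the list alone, adjusted p = 0.0587 with an estimated correlation). In total 1588 genes passed at ZT5, 2216 at ZT8 and 3375 at ZT12. With only the 2 pairs of each time fitted these counts were 3260, 4314 and 1851, and the ZT5 count was 358 without the Col-0 ZT5 pair, an omission chosen after seeing the data.

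**Figure D3:**
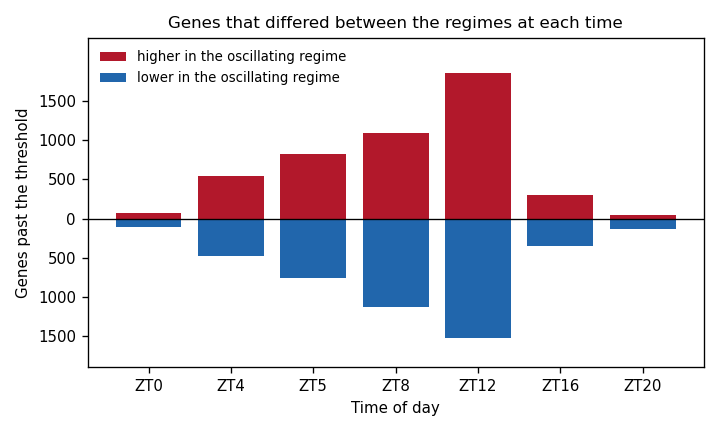
Number of genes past the threshold at each time of day, with bars above 0 for genes higher and below 0 for genes lower in the oscillating regime, both genotypes fitted together. The count was highest at ZT12 (1854 higher, 1521 lower) and lowest at ZT0 (68 higher, 102 lower). Without rescaling of TPM these were 1527 higher and 1538 lower at ZT12, and 122 and 99 at ZT0.

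Outside the warm window both regimes were at 17 °C by the growth protocol, apart from its edge at ZT4. At ZT4 8 of 36 heat shock genes were already higher, so averages outside the window include a time with raised heat shock genes. Over these times COR15A and COR15B, chloroplast proteins of cold acclimation, were higher in the oscillating regime. They had log2 differences of 3.72 ± 0.55 and 3.52 ± 0.60 (SE, adjusted p = 0.00212 and 0.0044, 8 of 8 pairs), and the dehydrin RAB18 and LEA7 were 2.46-fold and 2.48-fold higher. RAB18 was also 2.54-fold higher in the warm window (6 of 6 pairs, limma adjusted p = 0.000294). PDF2.1, which fell in the warm window, fell over these times too, to 0.219 of its constant level (0 of 8 pairs higher, limma adjusted p = 0.00503). Of the 18 cold response genes 2 were higher and 1 lower (5 and 1 adjusted over the list alone), and the list did not pass (median 0.21, adjusted p = 0.0685, adjusted p = 0.694 with an estimated correlation), but had 0.0429 without ZT4 and 0.0286 without ZT8. COR15B had 4.11 without ZT4, and 2.90 without ZT20, where it did not pass (adjusted p = 0.05). LHCB2.1, LHCB2.2 and LHCB2.3, antenna proteins of photosystem II, fell by 1.80, 1.92 and 2.29. LHCB2.1 did not pass without ZT0, ZT16 or ZT20, nor LHCB2.2 without ZT0, ZT8 or ZT20 (adjusted p up to 0.157 and 0.177). Of the 19 antenna genes 13 fell (16 adjusted over the list alone, adjusted p = 0.186 with an estimated correlation). All 3 seed storage markers were higher (3 adjusted over the list alone, adjusted p = 0.000211, adjusted p = 0.0637 with an estimated correlation). Their mean TPM was 0.482 to 1.39. The auxin (median 0.16), PIF-associated (0.15) and abscisic acid and dehydration (0.16) lists were higher (adjusted p = 0.0425, 0.0368 and 0.00373). The salicylic acid and defence (-0.15), dark and sugar (-0.72) and clock (-0.30) lists were lower (adjusted p = 0.0207, 0.0207 and 0.0448). With an estimated correlation none of these lists passed (adjusted p = 0.186 to 0.567). In total 548 genes rose and 572 fell, against 1266 and 334 without rescaling of TPM. The total of 1120 was 560 without ZT4, 681 without ZT8, 350 without ZT16 and 362 without ZT20.

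At ZT20 CCA1 and LHY were lower by log2 differences of -3.04 and -2.37, and COR15B and COR15A higher by 5.39 and 5.13. Antenna genes were lower at both ZT20 and ZT0, with 13 and 16 of 19 past the test (19 and 17 adjusted over the list alone, adjusted p = 0.0214 and 0.0116 with an estimated correlation). At ZT4, the time of the temperature step, HSP70-4 was already higher by 2.96 ± 0.17, at 57.2 against 5.32 TPM in Col-0, and DIN6 and DIN1, genes induced by darkness and low sugar, were lower by log2 differences of -3.08 and -2.94. All 4 genes of the dark and sugar list fell at ZT4 (4 adjusted over the list alone, adjusted p = 0.00444 with an estimated correlation). Of the 36 heat shock genes 8 were higher at ZT4 (17 higher and 1 lower adjusted over the list alone). The heat shock list had adjusted p = 9.48e-09, and adjusted p = 0.00444 with an estimated correlation. At ZT16 RD29A rose by 3.59 and HSP90.1 by 1.97, and PDF2.1 fell by 3.73. Counts were 170 genes at ZT0, 1012 at ZT4, 643 at ZT16 and 186 at ZT20, and 27, 1529, 2284 and 341 with only the 2 pairs of each time. The ZT16 count was 340 without ZT5, 326 without ZT8 and 1041 without ZT12, and the ZT20 count was 117 without ZT4, 99 without ZT5 and 117 without ZT8.

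**Figure D4:**
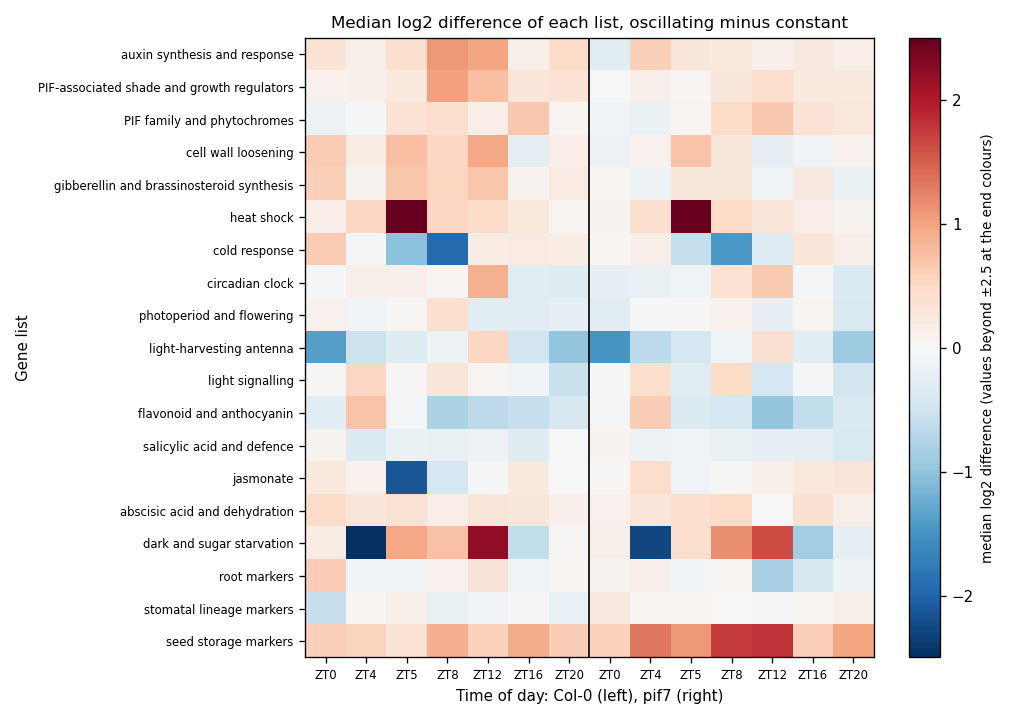
Median log2 difference between the oscillating and constant regimes of each of the 19 gene lists (rows) at each time of day in Col-0 and pif7 (columns), 1 pair of libraries per column, with red for higher in the oscillating regime. Over both genotypes the heat shock list had a median of 3.11 at ZT5 and the antenna list -1.43 at ZT0.

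Between the genotypes few genes differed at constant temperature. MRD1 (AT1G53480) was higher in pif7 by 5.55 ± 0.18 (SE, adjusted p = 3.37e-11, 7 of 7 pairs), and QQS, an orphan gene of starch metabolism, by 1.57. WEB1, a protein of chloroplast movement, and HCF243, a photosystem protein, had log2 differences of -1.16 and -1.07. By camera the PIF-associated (median -0.08), PIF and phytochrome (-0.05) and jasmonate (-0.47) lists were lower in pif7 at constant temperature (adjusted p = 0.0252, 0.0211 and 1.12e-09). With an estimated correlation all had adjusted p = 0.59. The auxin list did not pass at constant temperature (median -0.04, adjusted p = 0.0772). In the oscillating regime's warm window MRD1 and QQS were again higher, and IAA29 was lower by -3.00 ± 0.36 (SE, adjusted p = 0.00144, 0 of 3 pairs higher), with SAUR22 at -1.92, YUC8 at -1.38, HFR1 at -1.31 and PRE1, a growth-promoting helix-loop-helix factor, at -1.17. IAA29, SAUR22, YUC8, HFR1 and PRE1 did not pass without ZT8 (adjusted p = 0.0802 to 0.909) or without ZT12 (0.0699 to 0.509), nor SAUR22 without ZT4 or ZT20 (0.0604 and 0.0712). IAA29 had -3.69 without ZT5 and -2.41 without ZT8. Of the 32 auxin genes 3 fell (17 adjusted over the list alone, adjusted p = 0.00379 with an estimated correlation), and of the 21 PIF-associated genes 2 fell (14 adjusted over the list alone, adjusted p = 0.00118 with an estimated correlation). Of 14 cell wall loosening genes 1 fell (6 adjusted over the list alone, adjusted p = 0.00211 with an estimated correlation). The 3 seed storage markers were higher only when adjusted over the list alone (3 of 3, median 0.68, adjusted p = 3.01e-06, adjusted p = 0.00726 with an estimated correlation). Stomatal lineage markers had a median of 0.23 with 7 of 7 above 0, and root markers -0.17 with 6 of 19 (adjusted p = 0.00208 and 0.000348, adjusted p = 0.102 and 0.183 with an estimated correlation), and root markers had 0.529 without ZT12. Heat shock had a median of -0.10, light signalling -0.15, gibberellin and brassinosteroid synthesis -0.29, cold response -0.23, and the PIF and phytochrome list -0.06 (adjusted p = 0.000703, 0.000703, 0.000703, 0.00287 and 0.0275). With an estimated correlation these 5 had adjusted p = 0.0802, 0.183, 0.0641, 0.362 and 0.362. Cold response did not pass without ZT12 (0.393), nor the PIF and phytochrome list without ZT5 or ZT8 (0.313 and 0.123). Counts were 19 genes in the constant regime, 25 in the warm window and 76 over all times and regimes. The count of 25 was 5 without ZT8, 5 without ZT12 and 12 with only the pairs of the comparison. The count of 76 was 37 without ZT4, 45 without ZT5, 31 without ZT8, 37 without ZT12 and 45 without ZT20.

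**Figure D5:**
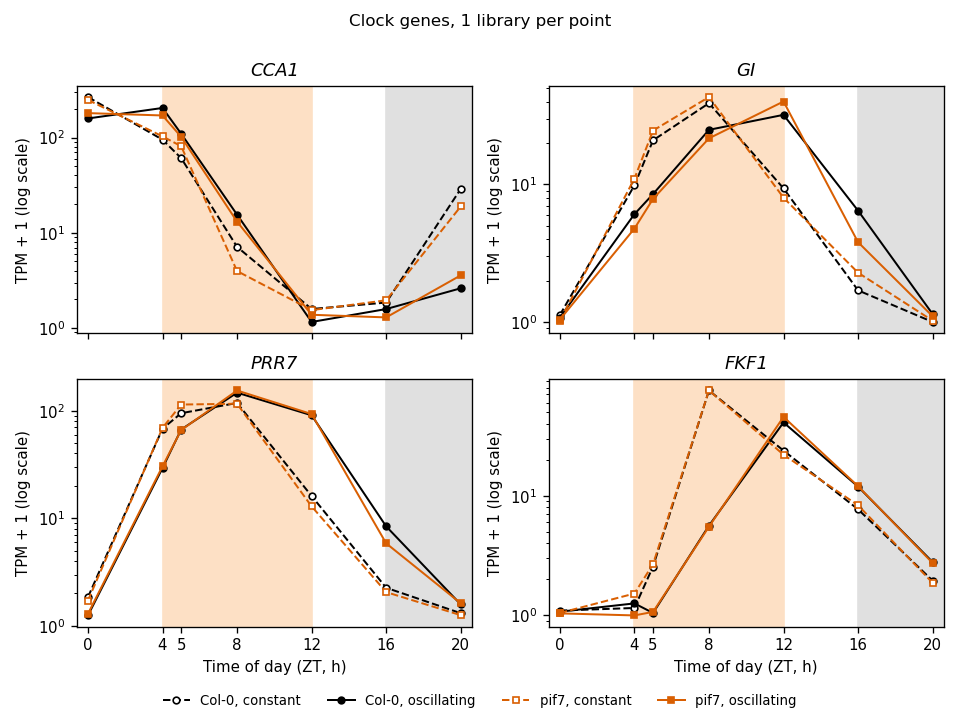
TPM + 1 on a log axis against time of day for the clock genes CCA1, GI, PRR7 and FKF1, with 1 library per point, Col-0 in black, pif7 in orange, constant regime dashed and oscillating regime solid, the warm window shaded orange and darkness grey. FKF1 in Col-0 stood at 74.6 TPM in the constant and 4.62 TPM in the oscillating regime at ZT8.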

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

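The tests of the lists' genotype-by-regime differences were chosen before the data were examined. The bounds for every test of an explanation, and for every count of regrouped labels in the other parts, were written down only after the results had been seen. Leaving out single times for the lists was chosen after seeing the data. The tests of depth on matched genes and of tissue shares were also chosen after the differences had been seen, and the rescaling alone holds the median of all genes near 0, so the test of depth rests on the matching for level and length.

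The auxin and PIF-associated lists differed between the genotypes in their warm window effect, by medians of -0.68 and -0.36 log2 units. Greater depth of the pif7 libraries, 1.35 to 1.62 times that of Col-0 at the window times of the oscillating regime, is argued against by 952 genes outside the lists with a like mean level and length, whose median was 0 against -0.59 for the 53 members, with -0.13 the lowest median of 1000 matched sets. A smaller warm step in the pif7 seedlings is argued against, mainly at ZT5, by the heat shock list, whose median difference was 0.02 (quartiles -0.14 and 0.11). Even so, in the oscillating window itself its median pif7 minus Col-0 was -0.10, with 3 of 36 members above 0. That difference had adjusted p = 0.000703, and adjusted p = 0.0802 with an estimated correlation. Over both genotypes the list rose most at ZT5, with medians of 3.11 at ZT5, 0.54 at ZT8 and 0.23 at ZT12. The auxin medians of the genotypes parted at ZT8 and ZT12, and the heat shock list cannot show equal warmth then. Root markers had a median difference of -0.21 and stomatal lineage markers of 0.15 (adjusted p = 8.64e-05 and 0.0207, adjusted p = 0.193 with an estimated correlation for both), but without ZT12 neither passed (0.901, in the other direction, and 0.874, or 0.192 without ZT8), while the members had -0.48 with 47 of 53 below 0, which argues against a different share of tissues in the ZT12 libraries as the whole cause. The 3 seed storage markers also differed, by a median of 0.70 (adjusted p = 0.0148 with an estimated correlation). Their mean TPM was 0.432 to 3.19. The test of tissue shares did not weigh them and bears only on ZT12. A need of the listed genes for PIF7 and less warmth in pif7 after ZT5 stay open. So does a difference between pools of seedlings, with 1 library per condition.

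The jasmonate list differed between the genotypes by a median of 0.79. In the constant regime pif7 minus Col-0 had a median of -0.47 with 0 of 13 members above 0 (adjusted p = 1.12e-09, adjusted p = 0.59 with an estimated correlation), against 0.04 in the warm window of the oscillating regime (adjusted p = 0.965). By time, the constant regime had medians of -1.69 at ZT5 and -0.60 at ZT8, with 13 of 13 members lower at both, and -0.31 to 0.21 at the others. In the constant Col-0 library at ZT5 JAZ10 stood at 20.5 TPM and AOC1 at 72.2, against 3.07 and 21.5 in pif7. Without ZT5 the median of 0.79 was 0.27, with 12 of 13 members still above 0, so a single library with induced jasmonate genes could account for most of the size but cannot be told apart from a difference between the genotypes, as no second library of that condition exists.

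Further differences between the genotypes' warm window effects were a median of -0.39 for cell wall loosening, -0.31 for gibberellin and brassinosteroid synthesis, and 0.70 for the 3 seed storage markers. At ZT12 oscillating minus constant medians in Col-0 and pif7 were 0.97 and -0.21 for cell wall loosening and 0.69 and -0.11 for gibberellin and brassinosteroid synthesis, while root markers differed too (0.32 and -0.82). Without ZT12 gibberellin and brassinosteroid synthesis did not pass (adjusted p = 0.134), and cell wall loosening had adjusted p = 0.0247. In data outside the comparisons, 13 assembled loci that overlap no reference gene stood above 5 TPM in every library, the highest on chromosome 1 from 2407535 to 2408083 at 41.6 to 185.7 TPM.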

How the results depend on the processing

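Omission of the Col-0 ZT5 pair, the nuclear genes alone, removal of a gene length trend, and left-out times for gene lists were alternatives chosen after seeing the data. Of 280 counts under all alternatives 235 stayed within 1.5 times the reported count. Of 25735 settings for single genes 24460 kept their side of the threshold, 892 lost and 383 gained a call, and 0 reversed. Settings past the threshold in neither fit counted as kept, for genes and for the lists that follow. The shares kept therefore do not show how often a call held. Time of day has no direction and could not reverse. Among 2489 settings for gene lists 2115 kept their side of the threshold, 299 lost and 72 gained a call. The 3 that reversed, all in the genotype-by-regime difference, were cold response without ZT5 (adjusted p = 0.864, from 1.42e-07 over the left-out times), root markers without ZT12 (0.901, from 7.38e-06) and heat shock without the Col-0 ZT5 pair (3.34e-13), the last by construction, as it sets windows with and without ZT5 side by side.

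With only the pairs of the comparison, and so fewer samples, the warm window gave 2 genes in Col-0, 0 in pif7 and 2323 in both, the single times 27 (ZT0), 1529 (ZT4), 3260 (ZT5), 4314 (ZT8), 1851 (ZT12), 2284 (ZT16) and 341 (ZT20), and pif7 minus Col-0 in the warm window 12. This alternative for the genotype difference over all times is the reported design and was not run again. Time of day gave 12906 genes with all 28 libraries, which add samples and also the oscillating regime. With no filter the genotype-by-regime difference gave 1 gene, and with a mean TPM of at least 5 the constant genotype difference gave 12, with fewer genes tested. Without the Col-0 ZT5 pair ZT5 gave 358, ZT16 341, ZT20 99 and the genotype difference over all times 45. With the length trend removed ZT16 gave 1032; the cause was not tested.

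Over the left-out times, counts ran from 23 to 925 (Col-0 window), 29 to 766 (pif7 window), 1256 to 3955 (both), 0 to 4 (genotype by regime), 350 to 1234 (outside), 326 to 1041 (ZT16), 99 to 204 (ZT20), 5 to 36 (genotype, window) and 31 to 75 (genotype, all times). Without rescaling, the median of all genes moved to 0.109 outside the window, 0.182 at ZT16 and 0.145 at ZT20, and the share of calls that were higher went from 48.9% to 79.1% outside the window and from 45.9% to 78.1% at ZT16. Depth could not be turned into counts, so its limit on low genes was not measured.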

Other observations

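The tests of time shift and of the gene length trend below were chosen after seeing the data, and the bounds for the regrouped labels were written after their counts were seen.

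For clock genes, the oscillating course matched the constant one best after a delay. Its median was 2 h in Col-0 (23 of 23 genes later) and 1.5 h in pif7 (22 of 23). Over 3725 rhythmic genes the medians were 1.5 h and 1 h. This estimate is the best shift of a whole course and not a comparison of measured peak times. The same estimate between the genotypes in the constant regime gave a median of 0 h. That argues against spread between libraries within a regime, but cannot show a difference in collection between the regimes. Collection over 1 h early is argued against for the oscillating ZT5 libraries by the heat shock list's median of 3.11 at ZT5. Collection over 1 h late is argued against for the constant ZT16 libraries by the dark and sugar list, which changed by a median of -0.79 from ZT12 to ZT16. Neither value bears on the libraries of other times. The shift of rhythmic genes differed with their peak time. Genes with a peak at ZT12 had medians of 2 h in Col-0 and 2 h in pif7. Those with a peak at ZT16 had 1 h and 0.5 h, and those at ZT20 1 h and 0 h (70.4% and 45.4% later). No test set a later phase of the clock apart from a delay of rhythmic genes in general, so both stay open. Changes of level at single times can also move the best shift of a course. No test set such changes apart from a delay, so they stay open as well. Errors of collection time under 1 h stay open too, and so do larger ones in the libraries of other times.

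Regrouped labels gave fewer genes than the real ones in most comparisons. For the warm window over both genotypes 1 of 32 splits, the real one, gave as many as 4084 (highest other 36). For the times outside it 1 of 100 gave 1120 (highest other 12), and for time of day 1 of 100 gave 6429 (highest other 553). These shares are under 0.05, which argues against a random assignment of labels to libraries. The splits counted the pairs of both genotypes at a time as independent. With 1 library per condition they cannot exclude differences between pools of seedlings. The warm window in Col-0 (927, highest other 0) and in pif7 (795, highest other 0) had 4 splits each. So did the genotype difference in the window (25, highest other 1), and 4 splits are too few for a share under 0.05. The genotype-by-regime difference had a real count of 0 (highest other 1), so each of its 10 splits gave as many by definition. For pif7 minus Col-0, 2 of 64 splits gave as many as 19 in the constant regime and 2 of 100 as many as 76 over all times. Both shares are under 0.05, but the highest others were 1569 and 1638, so these counts cannot exclude chance. The counts of 1569 and 1638 point to a structure of the samples. The first component of the pif7 minus Col-0 differences held 52.7% of their variance, and its loadings had a rank correlation of 0.57 with gene length across genes. With the length trend removed the split of 1569 gave 4 genes and the real one 17. Over all times the split of 1638 then gave 137 and the real one 70, and 2 of 100 splits still gave as many as the real one, so part of the structure was left.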
